A study of Mus musculus with 20 samples.

How the data were processed

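RNA from quadriceps muscle of 20 male C57BL/6J mice, 10 born to dams on a high-fat diet (mHFD) and 10 to dams on a low-fat diet (mLFD), had been hybridised to Agilent mouse 60-mer arrays with 2 colours. Per the labels, each sample was labelled with Cy5 and hybridised against a Cy3-labelled equimolar pool of all samples, starting from 200 ng of total RNA. Dyes were not swapped. A positive log ratio therefore means more RNA in the sample than in the pool, and the pool cancels when groups are compared. The arrays lay on 5 slides of 4 arrays. Each slide carried 2 mHFD samples, at positions 1 and 3, and 2 mLFD samples, at positions 2 and 4, so slide was balanced over the groups and position was not, so that linear and curved position effects can be fitted beside the groups, and an effect alternating between odd and even positions cannot. All arrays were scanned on one day.

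Per the file headers, spots were read with Agilent Feature Extraction 10.7.3.1, and probe coordinates refer to mouse build mm9 (NCBI 37). The deposited scanner files hold spot intensity values for both dyes, local background intensity, flags, and a log10 ratio of Cy5 over Cy3 that the authors' scanner software had already background-subtracted and dye-normalized. The authors also deposited a table of log2 values for 19377 spots that they had processed to an equal median in every column, and the labels used here do not give its scale, centring or direction. Compared with the scanner values, its columns had a gene-centred correlation of 0.994 or more with the log2 Cy5 median signal corrected by the deviation of Cy3 from its mean over arrays, and 0.686 or more with the log2 Cy5 median signal alone. Every column had a median of 7.54. The table was therefore read as log2 Cy5 values corrected by Cy3 and used as an alternative. How the authors corrected the background and scaled the columns remains unknown.

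From the scanner files, mean signals were background-corrected with normexp (offset 50), and log2 ratios were normalized by loess within each array, with control spots and non-uniformity outliers at weight 0. Outlier spots and the 1377 control spots were then left out, saturated spots were kept, and the spots of a probe were averaged. Of 39429 probes, the 19206 well above background in Cy5 on at least 10 of the 20 arrays were tested, which represent 15303 gene names. Names came from the scanner files and were updated through RefSeq transcript identifiers of assembly GRCm38, which matched 27234 probes; the file's name was kept otherwise. No gene models of build mm9 were used here, so exon and UTR positions of probes are not given. A gene was represented by its brightest probe.

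Groups were compared with moderated linear models of limma 3.58.1 in R 4.3.3 on the log2 scale, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. The Nr4a1 difference was also tested by permuting the arrays 100000 times. Gene lists of pathways and cell types, 38 in all, were written before the data were examined. The 37 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. For these list tests, a value missing because of an outlier flag was filled with the mean of its group. This choice was made after list results without the filling had been seen, and both are given in the closing section. Named genes were taken by a rule fixed beforehand: the Nr4a family, up to 12 genes per direction past the threshold, genes of smallest p up to 10 per direction, the 4 members of smallest p for each list past the threshold and for the immediate early and insulin lists, and the 2 brightest members of each cell type list. A few further genes are named below as chosen after their values were seen.

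The number of probes well above background in Cy5 ranged from 15506 to 23410 per array, and the factor by which the software had scaled Cy5 ranged from 1.15 to 6.10, against 1.28 to 1.96 for Cy3. The number of arrays limits the precision: the median standard error of a group difference was 0.0609 on the log2 scale. The steps were tested on simulated log ratios drawn with each real probe's SD, in which 69% of 100 probes changed by 0.3 and 94% of 100 probes changed by 0.6 on the log2 scale were recovered among 19206 probes. Of 171 calls in that simulation 8 were on unchanged probes, and a separate simulation with no changed probe gave 0 calls. Simulated genes were independent of each other, unlike genes on the real arrays, so list tests are less exact than this. The recovered shares also depend on how many probes changed, because many calls relax the Benjamini-Hochberg cutoff. On the real arrays only 1 probe passed, so the cutoff was stricter and these shares do not carry over to them. Litters are not labelled, and up to 4 siblings could share a group. Where siblings did, the mice were not independent and the p-values may be too small. Alternatives covered background correction, normalization, the Cy5 channel alone, the authors' table, the filter, slide, position, replicate number, array weights, the variance model, each array and slide left out, thresholds, the probe rule and the list tests.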

Results

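Gene expression was measured in the quadriceps, a thigh muscle, of 6-week-old male mice whose mothers had eaten a high-fat diet (40% of energy from fat) or a low-fat diet (10%) from 3 days before mating through lactation. All offspring ate the low-fat diet after weaning, so the groups differed in the maternal diet. Each group held 10 mice, called mHFD and mLFD. Values are log2 ratios of a sample to a pool of all samples, and differences are mHFD minus mLFD with the limma standard error (SE), n = 10 per group. The title of the series places Nr4a1 at its centre, so the values of that gene here are not independent evidence. Between 15506 and 23410 probes per array were well above background in the sample channel, on average 18977 in mHFD and 19531 in mLFD.

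Nr4a1, an orphan nuclear receptor of the immediate early type that acts in muscle metabolism, was higher in muscle of mHFD offspring. Its log ratio averaged 0.24 ± 0.37 (SD, n = 10) in mHFD and -0.32 ± 0.27 (SD, n = 10) in mLFD, a difference of 0.56 (SE 0.13) or 1.48-fold with a 95% interval of 1.23 to 1.78. All 10 mHFD samples lay above the mLFD mean, and 5 lay above the highest mLFD sample. Few random assignments of the arrays to the groups gave a difference as large (two-sided permutation p = 0.00140), and limma gave p = 0.000261 without adjustment. The difference did not pass the correction over all probes (adjusted p = 0.679). The probe lies on chromosome 15, 101105071 to 101105130. Within slides 1 to 5 the difference was 0.77, 0.69, 0.77, 0.34 and 0.24. With slide as a block it was also 0.56, which the balanced layout fixes in advance. The difference was 0.53 (unadjusted p = 0.0573) when arrays were only median-centred. The related receptor Nr4a2 had a difference of 0.34 (SE 0.14, unadjusted p = 0.0211, adjusted p = 0.689) on its brighter probe and 0.13 (p = 0.127) on the other. The probe for Nr4a3 was not well above background on any of the 20 arrays.

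**Figure D1:**
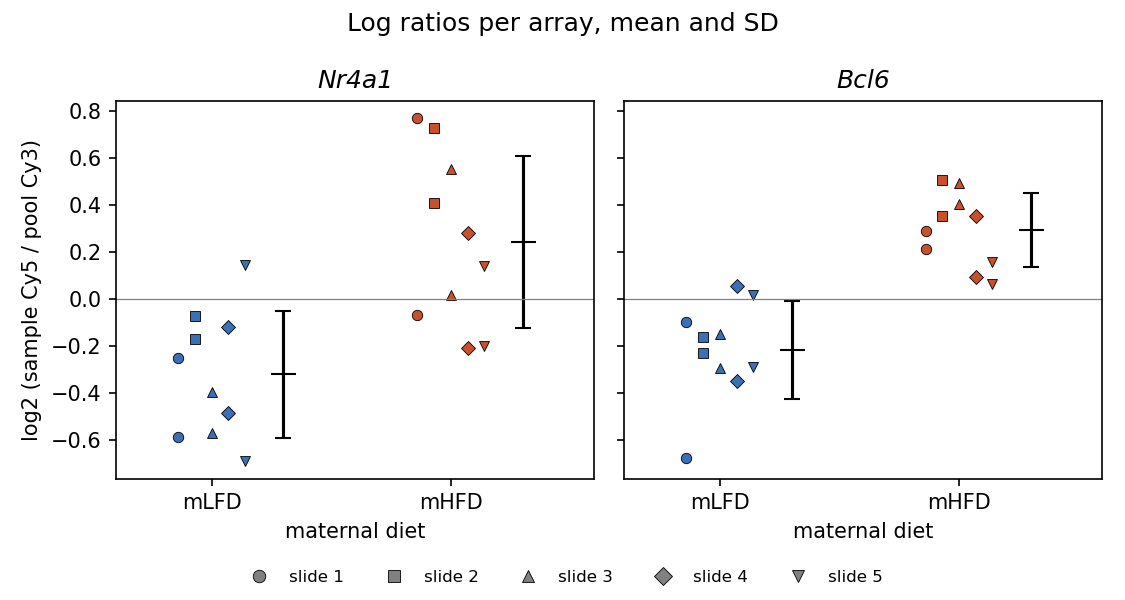
Log2 ratio of sample to pool (vertical axis) for Nr4a1 and Bcl6 in each array of the mLFD and mHFD groups, with symbols for the 5 slides and bars for the mean and SD of 10 arrays. The 10 mHFD values of Bcl6 all lie above the 10 mLFD values, whereas 5 of the 10 mHFD values of Nr4a1 do.

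Over all 19206 probes, 1 passed the threshold, and it represents Bcl6, a transcriptional repressor known from lymphocytes and from metabolic tissues. Bcl6 was 1.43-fold higher in mHFD, a log2 difference of 0.51 (95% interval 0.35 to 0.67), with means of 0.29 ± 0.16 and -0.22 ± 0.21 (SD, n = 10 each) and an adjusted p of 0.0244. Every mHFD sample exceeded every mLFD sample, and the difference had the same sign in 5 of 5 slides (0.64, 0.63, 0.67, 0.37 and 0.25). The probe lies on chromosome 16, 23965160 to 23965219. The call was kept with slide as a random block (difference 0.51, adjusted p = 0.0162). It was lost with slide as a fixed block (0.51, adjusted p = 0.0699), with position on the slide as a covariate (0.55, adjusted p = 0.0570) and when any of 10 single arrays was left out, while the difference stayed between 0.46 and 0.54 over all 20 such fits. Over the other settings its adjusted p ranged from 0.0124 to 0.99999, the highest with median centring. No probe passed in the lower direction. Without adjustment, 1371 probes had p under 0.05, 774 higher and 597 lower, where 960.3 would be expected by chance from independent tests. With position as a covariate the count was 940, below that expectation. In the Cy3 channel, which held the same pool on every array, the count between the arrays of the groups was 1571. That count used the signal of Cy3 alone, scaled by each array's 75th percentile, so it is not on the measure of the log ratios. The Cy5 channel alone, scaled in the same way, gave 1398.

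The genes of smallest p after Bcl6 did not pass the correction and are given as values. On the higher side, the amino acid transporter Slc38a2 differed by 0.42 (SE 0.09, adjusted p = 0.507) and Abtb2 by 0.25 (SE 0.05, adjusted p = 0.507). The salt-inducible kinase Sik1 differed by 0.48, Shisa2 by 0.37, the transcription factor Cebpb by 0.31, Ndel1 by 0.20, Ccdc117 by 0.18 and Ints13 by 0.16, each with an adjusted p of 0.679. A dimmer probe of Ndel1 gave -0.03. On the lower side, Acvr2b, a receptor for myostatin and activins, differed by -0.41 (SE 0.11) and Scube2 by -0.23 (SE 0.05), although a dimmer probe of Scube2 gave 0.00045. The proteoglycan gene Bgn differed by -0.21, Cenpw by -0.25, the sulfurtransferase gene Tst by -0.23 (-0.20 on a dimmer probe), Exoc7 by -0.21, Ccdc88b by -0.21, Sfxn5 by -0.21 (0.03 on a dimmer probe), Tle6 by -0.20 and Wdfy4 by -0.16. Each lower gene had an adjusted p of 0.679.

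Of the 37 gene lists tested, 7 passed the threshold with the preset correlation, 3 towards higher and 4 towards lower values in mHFD. By camera with an estimated correlation 0 passed (smallest adjusted p 0.528, 2 lists at an unadjusted p under 0.05), and by fry 0 passed (smallest adjusted p 0.318, 3 lists at an unadjusted p under 0.05). No list passed without mHFD replicate 1 or without slide 1. Leaving out single arrays kept the call in 18 of 20 cases for the adipocyte, immediate early and unfolded protein lists, and in 14 for cholesterol synthesis, 10 for heat shock, 10 for tenocyte and 8 for extracellular matrix genes. Of 24 other settings, the call was kept in 22 for the adipocyte and immediate early lists, 20 for the unfolded protein response, 17 for tenocyte, 14 for cholesterol synthesis, 12 for heat shock and 10 for extracellular matrix genes. All fits in these tallies used the preset correlation. The estimated correlation and fry, by which no list passed, are not among them. The plot of list means shows that the interval over arrays excluded 0 for 2 of the 7.

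**Figure D2:**
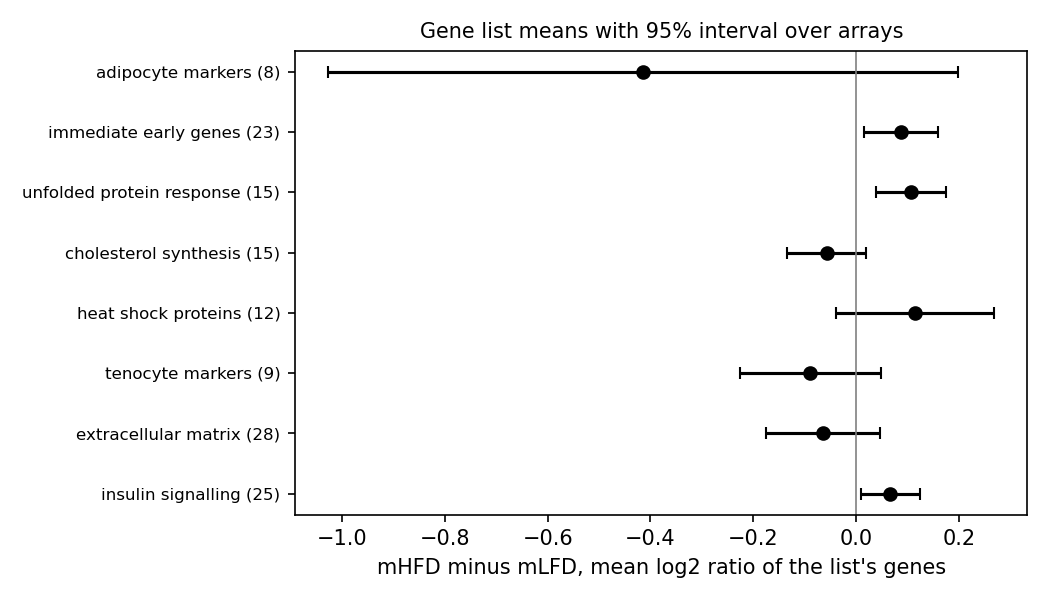
Difference between mHFD and mLFD in the mean log2 ratio of a list's genes (horizontal axis) for the 7 lists past the threshold and for insulin signalling, with the number of measured genes in brackets. Points are differences of means over 10 arrays per group and bars are 95% intervals over arrays. The intervals are not adjusted for the 37 lists tested, and the 7 lists were picked because they passed on these same arrays. They exclude 0 for immediate early genes, the unfolded protein response and insulin signalling, the last of which did not pass by camera (adjusted p = 0.123).

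Immediate early genes, which are induced within minutes to hours of a stimulus, were higher as a list (adjusted p = 0.0199, and adjusted p = 0.528 with an estimated correlation). Of 23 measured members 18 were higher and 5 lower, with a median of 0.06, and 3 passed adjusted over the list alone, against 0 over all genes. These were Atf3 at 0.59 (SE 0.18), Ier5 at 0.18 (SE 0.06) and Maff at 0.27 (SE 0.09), and Klf4 followed at 0.21 (SE 0.09). The classical members Fos, Egr1 and Dusp1, chosen after their values were seen, differed by 0.13, 0.01 and 0.04 (p = 0.110, 0.938 and 0.753). The list mean was higher on 5 of 5 slides. Over the other settings the median of the list ranged from 0.04 (no filter on dim probes) to 0.18 (Cy5 channel alone). The call was lost without mHFD replicate 1 (adjusted p = 0.0633) and without mLFD replicate 9 (0.0541), without slide 1 (0.0597), and with only probes well above background on all 20 arrays (0.107), a limit that Ier5 (15 arrays) and Maff (17 arrays) do not meet.

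The unfolded protein response, the set of chaperones and regulators induced by stress in the endoplasmic reticulum, was higher in 13 of 15 members (median 0.10, adjusted p = 0.0266, and adjusted p = 0.528 with an estimated correlation). Hspa5 and Hsp90b1, chaperones of the endoplasmic reticulum, differed by 0.25 (SE 0.10, p = 0.0174) and 0.22 (SE 0.09, p = 0.0282), Manf by 0.15 and Chac1 by 0.36 (SE 0.25, p = 0.151). No member passed, either over all genes or adjusted over the list alone. The list mean was higher on 5 of 5 slides, and the call was lost without mHFD replicate 1 (adjusted p = 0.0981) and without mLFD replicate 3 (0.0616), with median centring (0.0642), without slide 1 (0.0597), without slide 2 (0.0582) and with the adipocyte marker mean as a covariate (0.0501). Heat shock proteins were higher in 12 of 12 members (median 0.06, adjusted p = 0.0401, and adjusted p = 0.645 with an estimated correlation). Hspa8 differed by 0.27 (0.11 and 0.05 on its other probes), Hsp90aa1 by 0.32, Hspa1a by 0.25 and Bag3 by 0.06 (lower in the Cy5 channel alone), and 0 passed adjusted over the list alone. Hspa1a was well above background on 13 of the 20 arrays, and the brightest Hspa8 probe had no value in mHFD 03, mLFD 03 and mLFD 04. The list mean differed by 0.42 on slide 1 and by -0.09 on slide 5, and position as a covariate ended the call (adjusted p = 0.131). The median was 0.02 (adjusted p = 0.225) without mHFD replicate 1 and 0.0059 without slide 1. The call was also lost with median centring (0.0642), in the Cy5 channel alone (0.228) and in the authors' table (0.185). It was not made without the filling of missing values, either with genes measured on all 20 arrays (0.0957) or with the brightest such probe (0.109).

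The lists towards lower values were adipocyte markers, cholesterol synthesis, tenocyte markers and extracellular matrix. Adipocyte markers were lower in 8 of 8 measured members (median -0.39, adjusted p = 0.0168, and adjusted p = 0.645 with an estimated correlation). Cidea differed by -0.73 (SE 0.49), Cfd by -0.47 (SE 0.24), Cidec by -0.43 (SE 0.22, and -0.05 on a dimmer probe), Plin1 by -0.35 (SE 0.18) and Fabp4 by -0.13 (SE 0.16), and 0 passed adjusted over the list alone. The mean of the markers was -0.51 ± 0.52 in mHFD and -0.10 ± 0.76 in mLFD (SD, n = 10 each). Random assignments of the arrays to the groups often gave a difference as large (two-sided permutation p = 0.171). By slide the difference of the marker means was -1.05, -0.31, -0.49, -0.26 and 0.04. The call was lost without mHFD replicate 1 (adjusted p = 0.0633) and without mLFD replicate 1 (0.0529).

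Cholesterol synthesis genes were lower in 12 of 15 members (median -0.06, adjusted p = 0.0401, and adjusted p = 0.645 with an estimated correlation), with Fdft1 at -0.19 (SE 0.08), Sqle at -0.16 (SE 0.09), Mvd at -0.13 (SE 0.06) and Msmo1 at -0.11 (SE 0.07). Without mHFD replicate 1 the list's median was -0.04 (adjusted p = 0.177). The direction of Fdft1 did not hold in the Cy5 channel alone, and Sqle was well above background on 15 of the 20 arrays. Tenocyte markers, which come with tendon, were lower in 8 of 9 members (median -0.10, adjusted p = 0.0401, and adjusted p = 0.645 with an estimated correlation), among them Tnmd at -0.15, Fmod at -0.20, Kera at -0.16 and Cilp2 at -0.10, while the brightest, Thbs4, was at 0.0024 and changed sign with scaling. Extracellular matrix genes were lower in 22 of 28 members (median -0.05, adjusted p = 0.0469, and adjusted p = 0.664 with an estimated correlation), with Bgn at -0.21, Col1a1 at -0.34 (SE 0.12), Dcn at -0.20 and Loxl1 at -0.11 (-0.03 on a dimmer probe). No member of these 3 lists passed adjusted over the list alone. The extracellular matrix call was not made without the filling of missing values (adjusted p = 0.115 and 0.137). With position as a covariate the adjusted p was 0.222, 0.351 and 0.123 for the 3 lists, in the order given. The medians were then smaller in size, at -0.03 (with linear and curved position), -0.04 and -0.02. The list means were higher on slide 5 for cholesterol synthesis (0.01) and extracellular matrix (0.08), and on slide 4 for tenocyte markers (0.02).

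Insulin signalling, the pathway the series title refers to, did not pass (adjusted p = 0.123, and adjusted p = 0.645 with an estimated correlation). Of 25 measured members 16 were higher and 9 lower, with a median of 0.05 and 0 passing over all genes or adjusted over the list alone. The median was 0.02 without mHFD replicate 1 and 0.01 without slide 4. Irs2, an adaptor of the insulin receptor, differed by 0.56 (SE 0.21, p = 0.0164), the transcription factor Foxo1 by 0.31 (SE 0.14) and by 0.25 on a second probe, the kinase subunit Pik3ca by 0.15 (SE 0.07) and Pik3cb by -0.12 (SE 0.05). The Irs2 values spread widely in mHFD, from -0.90 (mHFD 08) to 1.40 (mHFD 05), with an SD of 0.73 against 0.21 in mLFD. The insulin signalling list did pass with the Agilent log ratio (adjusted p = 0.0156), with scaling between arrays (0.0453), in the Cy5 channel alone (0.00507) and without slide 3 (0.0169), and its adjusted p over the alternatives reached 0.361. Oxidative phosphorylation (median -0.03, adjusted p = 0.479), fast-fibre contractile genes (0.03, 0.455), slow-fibre contractile genes (-0.18, 0.149), glycolysis and glycogen metabolism (0.04, 0.248) and fatty acid uptake and oxidation (0.05, 0.0589) did not pass.

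The other cell type lists did not pass. Their medians were -0.09 for neutrophil and mast cell markers (adjusted p = 0.0771), -0.03 for satellite cells (0.207), -0.05 for macrophages (0.231), -0.06 for Schwann cells (0.246), -0.09 for endothelial cells (0.280), 0.03 for smooth muscle and pericytes (0.434), -0.02 for erythroid cells (0.577), -0.01 for lymphocytes (0.848) and 0.0019 for fibro-adipogenic progenitors (0.947). The endothelial gene Vwf differed by -0.25 (SE 0.08) and was the 1 endothelial member past the threshold adjusted over the list alone. The mean of the neutrophil and mast cell list differed by -0.27 (95% interval -0.53 to -0.01 over arrays, unadjusted for the 37 lists) and was lower on 5 of 5 slides. S100a9, a neutrophil gene, differed by -1.16 (SE 0.53, p = 0.0379). The differences of the brightest markers of the other types, of which Hba-a2, Cd4, Cd34 and Cdh15 changed sign under at least 1 other scaling, were Hba-a2 0.0029, Hba-a1 0.11, Itgam 0.06, Csf1r -0.06, Cd4 0.01, Cd3e 0.09, Mcpt4 -0.09, Egfl7 -0.09, Tagln 0.03, Acta2 0.07, Smoc2 0.07, Cd34 -0.0047, Pmp22 0.13, Prx -0.08, Cdh15 0.02 and Notch3 -0.15. Dimmer probes of Itgam (-0.0016 and -0.03), Cd34 (0.05) and Pmp22 (-0.01) had the opposite sign.

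The Cy3 channel held the same pool on every array and served as a negative control. No probe differed between the arrays of the groups in that channel by limma, 1571 probes had an unadjusted p under 0.05, and the Nr4a1 signal differed by 0.04 (SE 0.05, p = 0.411). A linear trend with position on the slide passed for 4145 probes in Cy3 and for 290 probes in the log ratios. The Cy3 counts are of that dye alone, without the loess step, so the 2 measures are unlike.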

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

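Of the tests in this part, those of position effects, of the general immediate early response, of the Cy3 against the Cy5 range and of splits balanced on every slide were chosen only after the result was seen. Single samples stood far from the other 9 of their group in 17 of 141 combinations of a named gene and a group, where chance gives about 1 in 20, or 7.05. The number after each gene is the gap to the nearest sample as a share of the group's range. In mHFD 08 these were Kera (0.626, high), Thbs4 (0.531, high), Ier5 (0.531, high), Chac1 (0.524, low) and Col1a1 (0.484, high). In mHFD 01 they were Hba-a1 (0.549, low), Sik1 (0.529, high) and Hspa1a (0.475, high). In mLFD 07 they were Hba-a2 (0.577, high) and Hba-a1 (0.495, high). In mLFD 05 they were Hsp90b1 (0.477, high), Cd3e (0.474, high) and Itgam (0.469, high). The others were Smoc2 in mHFD 06 (0.507, high), Pik3ca in mLFD 02 (0.497, low), Fdft1 in mLFD 06 (0.488, high) and S100a9 in mHFD 05 (0.474, high). Without mHFD replicate 8 the tenocyte list had a median of -0.13 and an adjusted p of 0.000463, but 10 of 20 such fits lost its call (adjusted p up to 0.152, without mLFD replicate 7), and with an estimated correlation its adjusted p was 0.645 on all arrays.

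The higher Nr4a1 in mHFD was weighed against technical sources. With position as a covariate the difference was 0.53 (95% interval 0.18 to 0.88). The linear trend's own part was 0.03 (95% interval -0.12 to 0.19). That interval excludes the whole difference of 0.56, which argues against a linear position trend as the whole source. With the Cy5 scaling factor as a covariate the difference was 0.55 (0.24 to 0.86). The factor averaged 3.37 (SD 1.74) in mHFD and 2.83 (SD 1.33) in mLFD. Groups this close left that covariate little room to move the difference, so it decides nothing about dim Cy5 signal. Adding the square of position also gave 0.53, but the layout balances that term over the groups, so it could not have moved the difference and tests nothing. With the mean of the 23 immediate early genes as a covariate it was 0.37 (0.07 to 0.68). That list was itself higher in mHFD, so a general response at death remains open. An effect alternating between odd and even positions is confounded with the groups, and shared litters and the maternal diet itself also remain open.

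The lower adipocyte markers may come from a smaller share of fat tissue in the mHFD muscle samples. The markers varied together within groups, with a median pairwise correlation of 0.862 (lowest pair 0.748, highest 0.945), as a varying share of fat would give. Being taken within groups, that correlation cannot show that the share differed between them. The brightest markers, Fabp4 and Cfd, differed by -0.13 and -0.47. Whether the share of fat differs between mice or in dissection was not tested. With position as a covariate the mean marker difference was -0.52 (95% interval -1.22 to 0.18). By camera at the preset correlation the list then kept its call (adjusted p = 0.000328). The tenocyte, extracellular matrix, cholesterol and heat shock lists lost theirs. That preset lies far below the correlation of 0.862 among these markers, so the kept call decides nothing about position. Without the covariate, camera with an estimated correlation gave the adipocyte list an adjusted p of 0.645. The linear trend's own part was 0.11 (95% interval -0.20 to 0.42), opposite in sign to the difference of -0.41, and its interval excludes -0.41. That comparison takes the difference as exact, although its own 95% interval over arrays was -1.03 to 0.20. The criterion also replaced a first one, an interval of the adjusted difference that excludes 0, after the first was seen not to be met. A linear trend is therefore not excluded as the source.

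Cy5 was dim on some slides, with a mean factor of 4.64 on slide 2 and 1.26 on slide 1. The log2 range of the Cy3 factor was 0.254 of that of Cy5, which argues against less material in both channels as the whole source. No biological explanation was tested.

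Chance was examined by splitting the 20 arrays freely into 10 and 10 in 100 ways, the real one included, and in 100 ways that kept 2 and 2 arrays on every slide as the real groups do. Free splits can also hold slide differences, which the real comparison cannot. For probes past the threshold, 5 free splits gave as many as the real 1 (highest other 3), so chance cannot be excluded by these, whereas of the balanced splits only the real 1 did (highest other 0). That result holds only for the fit without slide, rests on 1 probe, and 1 of 100 is the smallest share these splits can give. The balanced splits were also chosen after the result was seen and do not keep the odd and even positions of the real groups. Chance is therefore not excluded by them. With slide as a fixed block limma gave 0 probes in the real groups (1703 at an unadjusted p under 0.05), so every split would give as many. For probes at an unadjusted p under 0.05, 14 free splits (highest other 2803) and 7 balanced splits (highest other 1912) gave as many as the real 1371, so chance cannot be excluded. For gene lists, 38 free splits (highest other 14) and 50 balanced splits (highest other 15) gave as many as the real 7, so chance cannot be excluded.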

How the results depend on the processing

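The Cy5 factor, the adipocyte mean, curved position and both ways of using complete values for lists were added after seeing the data. Nr4a1 was higher in mHFD under the settings run here, from 0.49 to 0.64 on more than 1 slide and from 0.24 to 0.77 on single slides, and at 0.37 with the immediate early mean as a covariate; its side was judged by unadjusted p, a rule set after its p was seen. That p missed 0.05 with median centring (0.53) and within slide 4 (0.34) and slide 5 (0.24) alone, where 2 arrays faced 2. The count of 1 probe became 0 with the Agilent log ratio, median centring, scaling between arrays, Cy5 alone, the authors' table, slide as a fixed block, position (linear, or linear and curved), the adipocyte mean, and without slide 1, 2, 3 or 4, and 1371 at an unadjusted p under 0.05. Leaving out single arrays gave 0 to 1; it was 0 without mHFD 1, 3, 4, 5, 6 or 8 and without mLFD 4, 5, 7 or 9. The unadjusted count was 96 with median centring and 536 in the authors' table. The replicate block gave 2 probes; same-numbered samples correlated at -0.0099 to 0.354, with 8 of 10 pairs above 0.1, but they share a slide, samples on the same slide had a median of 0.153 across groups, and only 7 of 20 correlated best with their own number, so the numbers were not read as pairs. The 7 lists became 14 with the Agilent log ratio, 11 with scaling, 11 without a filter, 2 with probes above background on all arrays, 4 with the adipocyte mean, 0 without slide 1, 4 without slide 2, 13 without slide 5, and 0 with an estimated correlation or fry. Leaving out single arrays gave 0 to 9 lists, with 0 without mHFD 1, 2 without mLFD 3 and 4 without mHFD 5. With complete values only, 5 lists passed, and 6 with the brightest complete probe; heat shock and extracellular matrix lost their calls in both. With position in either form 5 lists passed, 3 of the 7 and also slow-fibre and neutrophil and mast cell genes. The causes were not tested. Directions turned for Fdft1 in Cy5 alone (0.0031), for fatty acid uptake and oxidation (-0.000505) and interferon response (-0.0203) with position in both forms, for glycolysis without slide 3 (-0.0420), and, with the adipocyte mean, for fatty acid and triglyceride synthesis (0.0602) and, by construction, the adipocyte markers (0.0086). Of 3044 comparisons of named genes 88 more, and of 1626 of lists 104 more, changed sign without a p under 0.05. Insulin signalling passed in 4 settings. Lists were not run with slide as a random block. The Cy3 control gave 0 by limma with slide as a fixed block (1529 at an unadjusted p under 0.05) and with position (458), the 2 alternatives run for it. Dim Cy5 on slides 2 and 3 limits probes near background.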

Other observations

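Of the tests in this part, the one of FoxO targets was chosen only after values of some of its members had been seen, and the lists of both tests were chosen after the leading genes had been seen. Outside the lists described above, glucocorticoid response genes had a median of 0.13 (adjusted p = 0.0662, and adjusted p = 0.664 with an estimated correlation), with 12 of 16 members higher. Cebpb was the 1 member past the threshold adjusted over the list alone, and of members chosen after their values were seen Zbtb16 differed by 0.25 (SE 0.11), Tsc22d3 by 0.30 (SE 0.13) and Fkbp5 by 0.12 (SE 0.20). Fatty acid and triglyceride synthesis genes had a median of -0.12 (adjusted p = 0.0831), and imprinted genes of -0.07 (adjusted p = 0.175). Ppargc1a, a coactivator of mitochondrial genes chosen after its value was seen, differed by 0.34 (SE 0.13, p = 0.0140), while mitochondrial biogenesis regulators as a list had a median of 0.00085 (adjusted p = 0.829).

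Nr4a1, Sik1, Cebpb and Ppargc1a are known targets of cAMP signalling, and Irs2 is a target of FoxO factors, so a raised activity of either may be a hypothesis. Of 9 measured cAMP-responsive genes outside the fixed lists 4 were higher and 5 lower (median -0.0068, p = 0.272 with an estimated correlation). Of these, 2 had an unadjusted limma p under 0.05, Pde4d at 0.30 and Ramp3 at 0.17. Of 23 FoxO targets 11 were higher and 12 lower (median -0.01, p = 0.937 with an estimated correlation), and 1, Pdk4 at 0.47, had such a p. Neither list was higher as a set. A median of 0 or lower was the criterion against either, set beforehand for cAMP and only after values had been seen for FoxO, but both medians lie within their SE over genes (0.05 and 0.03) and members went both ways, so neither hypothesis is excluded.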
